A study of Homo sapiens with 6 samples.

How the data were processed

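Total RNA of SW1353 cells was labelled and hybridised to Illumina bead arrays, 3 from control cells and 3 from cells given IL-1 at 0.5 ng/ml for 6 h, per the labels' protocols. The deposited table gives, per the file headers, an intensity signal and a detection p-value for each of 48784 probes on each array, with no background correction or normalization stated there. The authors' series matrix holds log2 values of the same arrays, and lumi is named in the submitters' processing notes, with settings not given in the sources used here. The correlation of those log2 values with log2 of the deposited signals lay between 0.983 and 1.00 per array. Their medians were 5.86, 5.87 and 6.50 on the control arrays and 5.87, 5.86 and 6.49 on the IL-1 arrays, in replicate order, so the 2 kinds of sample title differ in scale. Whether the authors normalized the 2 kinds apart stays unknown.

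Samples were grouped by their labels. The titles come in 2 kinds, Allstars (4 arrays) and Sample (2 arrays), each holding both groups, and this title series was used as a block in an alternative fit. Probes well above background numbered 13030, 12650 and 13357 on the control arrays and 12603, 11954 and 13070 on the IL-1 arrays. The median signal of detected probes over that of undetected ones was 7.12 and 7.38 on the Sample arrays and between 3.19 and 4.22 on the Allstars arrays. No slide numbers or scan dates were used here. No pair of arrays held identical values.

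Signals were background-corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3 (normexp, with the background inferred from detection p-values, and an offset of 16). Probes with a detection p under 0.01 on at least 3 arrays were kept, 13017 in all. Gene names came from GEO's platform annotation, in which 28085 probes had 1 gene, 13 had several and 20686 were not listed. Of the named probes, 28046 had a gene ID found in the RefSeq table, which changed 0 symbols. Of the kept probes 11408 had 1 gene and 1609 were not named. The probe with the highest mean over the 6 arrays stood for its gene, which gave 9078 genes, 1996 of them with more than 1 kept probe. Of the named genes 20 had other kept probes, 23 in all, and 0 of these had a fold change of opposite sign. PDE5A's other probe did not pass (limma adjusted p = 0.0688).

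Genes were tested with lmFit and eBayes with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over all genes tested and an adjusted p under 0.05. The design held treatment and no block, as the series states only 3 samples against 3. Both the difference of the response between title series (interaction) and a fit with title series as a block were run. Before the data were examined, 33 gene lists were fixed, and the 29 with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation was run beside it, and so was fry, which tests whether a list moves 1 way and does not set it against the other genes. Counts adjusted over the list alone used Benjamini-Hochberg within the list.

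The genes to be named were also set before the data were examined. They were the 10 with the highest and the 10 with the lowest log2 fold change among called genes whose 3 IL-1 arrays all lay on 1 side of the 3 control arrays. From each list came the 3 called members with the largest absolute fold change. In addition came, whatever their values, MMP1, MMP3, MMP13, ADAMTS4, ADAMTS5, TIMP1, TIMP3, IL6, CXCL8, PTGS2, NFKBIA, TNFAIP3, FOS, JUN, FOSL1, ATF3, SOX9, COL2A1, ACAN, IL1R1 and IL1R2. The rule gave 82 tested genes. Genes outside it are marked in the text as named after their values were seen.

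The fits were tested on simulated arrays of 9078 genes, 3 against 3, with the title series difference kept. Without the block, the step called 0% of genes changed by 0.5 on the log2 scale, 37.3% of those changed by 1, 84.0% of those changed by 2 and 100% of those changed by 4. With the block, it called 48.0%, 82.7%, 98.0% and 100%. Of 8878 unchanged genes 1 was called without the block and 4 with it. The simulated noise was independent between genes, and the simulated response was the same in both title series. These counts thus do not give the share of false calls in the data. The changed genes numbered 50, 75, 50 and 25, fewer than were called in the data. The adjustment depends on the number of calls, so these rates do not give the power of the real fits.

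Alternatives covered the replicate number and title series as blocks, Allstars arrays alone, no background correction, equal medians without the quantile step, the authors' deposited log2 values, other detection filters, all probes, eBayes without a trend, array weights and leaving out each array in turn. Probes without a gene name were left out of the tests of genes.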

Results

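Gene expression was measured in SW1353 cells, a human chondrosarcoma line that is widely used as a stand-in for chondrocytes. The cells were kept without serum for about 20 h and then given interleukin-1 alpha (IL-1) at 0.5 ng/ml for 6 h, or left without it. There were 3 control and 3 IL-1 samples, each hybridised to an Illumina bead array with 48784 probes. The sample titles come in 2 kinds, here called title series. The Allstars series holds control replicates 1 and 2 and IL-1 replicates 1 and 2, the Sample series holds control replicate 3 and IL-1 replicate 3, and the labels do not say what the kinds mean. Median signals were 67.2, 60.3 and 95.3 on the control arrays and 63.2, 63.2 and 91.5 on the IL-1 arrays, in replicate order. Between 11954 and 13357 probes per array were well above background (detection p under 0.01). Nothing states that the samples came from separate cultures, so p-values measure the spread between these samples, which may be technical, and the number of arrays limits the precision.

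The comparison asks which transcripts differ after 6 h of IL-1. Chemokines, cytokines, matrix metalloproteinases, NF-kB feedback genes and interferon-induced genes rose, many of them from below background. CXCL10, a chemokine that attracts T cells, rose from a mean log2 signal of 4.85 ± 0.04 to 14.27 ± 0.13 (SD, n = 3 each), at least 317-fold. PDK4, an inhibitor of the pyruvate dehydrogenase complex, fell from 7.60 ± 0.35 to 5.21 ± 0.54, at least 2.83-fold. Of 9078 genes tested, 552 rose and 267 fell (limma with Benjamini-Hochberg adjustment, adjusted p under 0.05), of which 424 and 110 changed at least 2-fold. With title series as a block, 1181 genes rose and 2015 fell, and all 819 genes called without the block were called. Each series holds as many control as IL-1 arrays, so a block cannot alter a fold change, and the direction was fixed in advance. Under the block and with array medians equalised in place of quantile normalization, 1358 rose and 1526 fell. The Allstars arrays alone gave 1048 rises and 1534 falls. Without control replicate 1 or 2, or IL-1 replicate 1 or 2, the count of genes dropped to 446, 455, 426 and 465. Without control or IL-1 replicate 3, the Sample arrays, it was 831 and 965. These fits had no block, nor did those cited below that left out an array. Leaving out 1 array also makes the shares of the title series unequal between the groups. The series difference then enters these fold changes and their p-values. With title series as a block, 0 of the 82 named genes lost a call.

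For a gene not well above background on any array of 1 group, the change is given as a lower bound. Such a gene passed the detection filter only through the other group, so shares of rises in lists and camera p-values follow partly from it. The bound sets the brighter group's mean against the dim group's mean after each dim value is raised to the lowest signal among the probes well above background on its array. Other changes are log2 fold changes ± SE from limma, with 3 arrays per group.

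**Figure D1:**
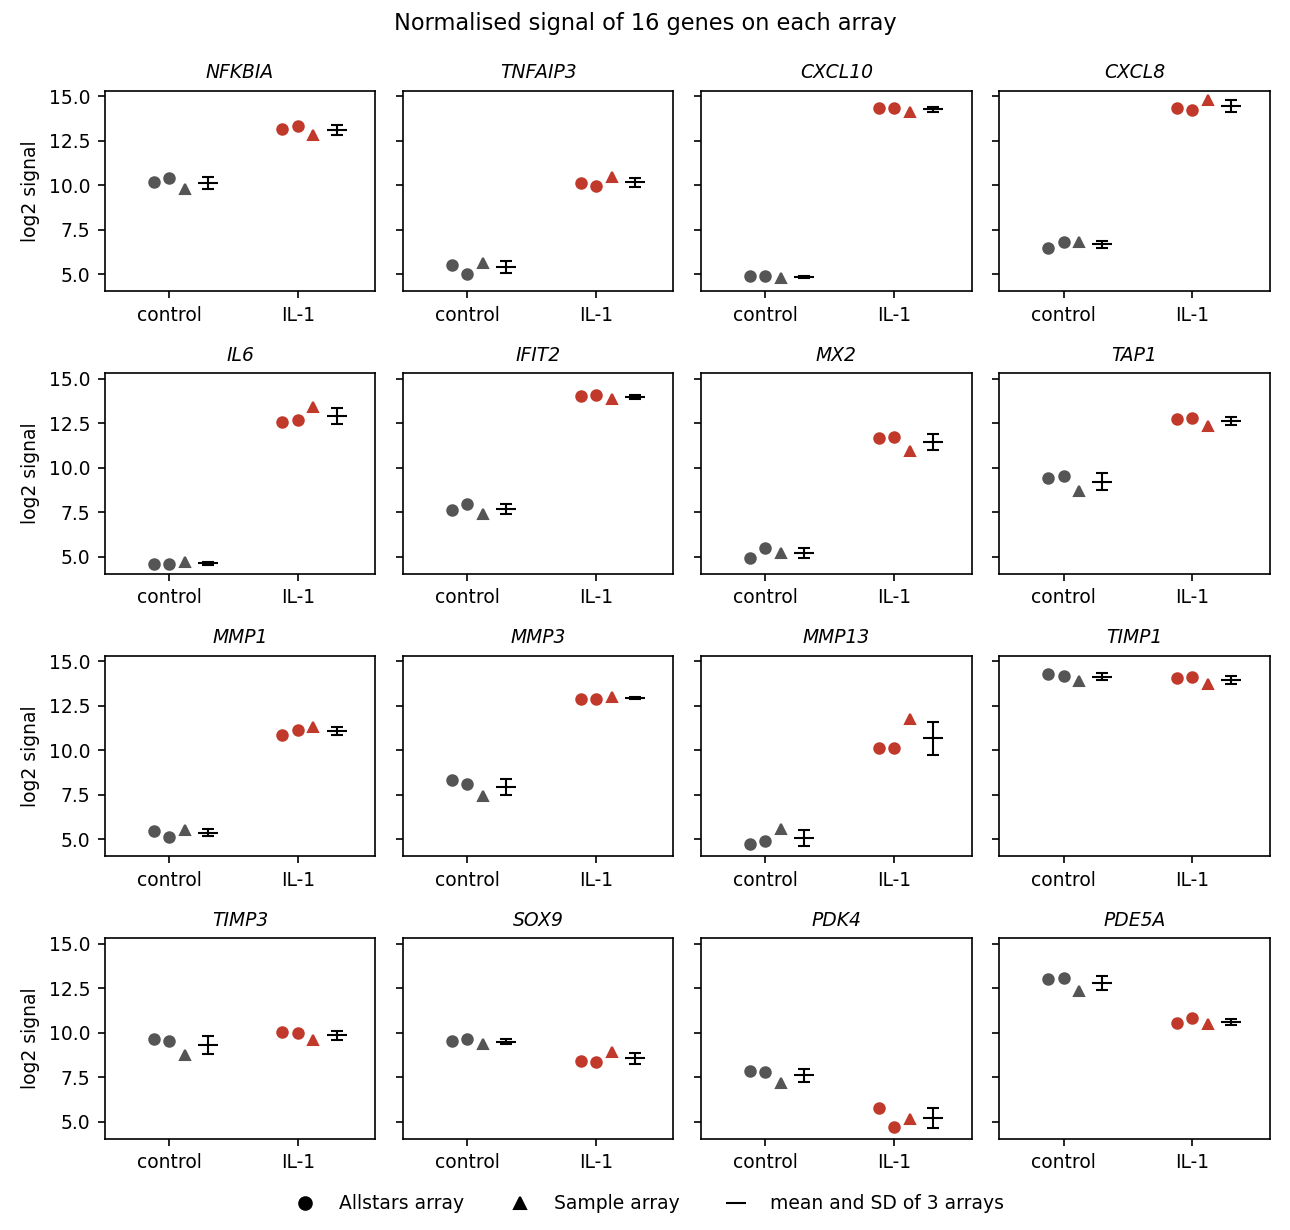
Normalised log2 signal of 16 genes on each of the 6 arrays, with circles for Allstars arrays, triangles for Sample arrays, and black marks for the mean and SD of 3 arrays per group. CXCL10 lies near 4.85 in the controls and 14.27 after IL-1, whereas TIMP1 lies at 14.12 and 13.96.

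Genes of NF-kB feedback and signalling rose as a group: 18 of the 19 measured members rose and none fell, with 18 adjusted over the list alone. TNFAIP3, which encodes the ubiquitin-editing enzyme A20, rose at least 18.4-fold (limma adjusted p = 9.68e-06). TNFAIP2 rose at least 11.7-fold. ZC3H12A, which encodes the ribonuclease regnase-1, rose by 4.30 ± 0.14, and NFKBIA, which encodes the NF-kB inhibitor IkB-alpha, by 2.98 ± 0.20 (7.89-fold; limma adjusted p = 6.91e-05). The list median was 2.09 (camera adjusted p = 1.84e-27, and adjusted p = 0.00682 with an estimated correlation).

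Of 11 measured chemokines 10 rose, and 10 did so adjusted over the list alone. Of 23 members with a named probe these 11 passed the filter, 5 of them without a control array well above background. CCL8, a monocyte attractant, rose by 7.89 ± 0.14, which is 237-fold. CXCL8, the neutrophil attractant also called interleukin-8, rose by 7.76 ± 0.19, which is 217-fold (limma adjusted p = 4.55e-07). CCL3 rose at least 96.3-fold and CCL3L3 at least 128-fold, but these are near-identical copies, so a probe of 1 may read the other. CCL4L1, a copy of CCL4, rose at least 62.2-fold, while the probe of CCL4, named after its value was seen, was well above background on 0 arrays. The group had a median of 5.00 (camera adjusted p = 2.90e-23, and adjusted p = 0.00682 with an estimated correlation). CXCL1 and CXCL2, singled out after their values were seen, were well above background on 0 arrays and were not tested.

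Cytokines and colony-stimulating factors rose in 11 of 14 measured members, with 11 adjusted over the list alone. Of 26 members with a named probe these 14 passed the filter, 8 of them without a control array well above background. IL6, a main inflammatory cytokine, rose at least 122-fold from 4.63 ± 0.07 to 12.88 ± 0.45 (SD, n = 3 each; limma adjusted p = 7.15e-07). IL1B rose at least 21.3-fold, and TNFSF13B, which encodes the B-cell factor BAFF, at least 25.7-fold, and another kept probe of TNFSF13B, well above background on 1 of 3 control arrays, differed by 4.42. IL36G, an IL-1 family cytokine outside the list, rose at least 45.3-fold. Its members had a median of 2.21, or 1.70 with genes at their bounds (camera adjusted p = 4.56e-18, and adjusted p = 0.0114 with an estimated correlation).

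Matrix metalloproteinases, which degrade extracellular matrix, rose in 6 of 11 measured members, and 7 rose and 1 fell adjusted over the list alone. MMP12, the macrophage elastase, rose at least 72.8-fold, or at least 40.1-fold by another kept probe. The collagenases MMP1 and MMP13 rose at least 35.2-fold and at least 26.1-fold (limma adjusted p = 1.14e-06 and 0.000210). MMP3, or stromelysin-1, rose by 4.97 ± 0.22, which is 31.3-fold. MMP10 and MMP7, the other risers, were named after their values were seen and rose by 3.24 ± 0.26 and 1.27 ± 0.21. The median of the list was 1.27 (camera adjusted p = 1.54e-08, and adjusted p = 0.0198 with an estimated correlation).

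Among 9 measured ADAM and ADAMTS proteinases, 2 rose, and 2 rose and 2 fell adjusted over the list alone; the list as a whole did not pass (camera adjusted p = 0.279). ADAMTS9 rose by 2.57 ± 0.30 and was well above background on 1 of 3 control arrays. ADAM17, the sheddase of tumour necrosis factor, rose by 0.77 ± 0.17, with limma adjusted p = 0.0275 that reached 0.127 without IL-1 replicate 1 and held in 1 of the 6 fits that left out an array. Its limma adjusted p was 2.59e-05 with title series as a block. The aggrecanases ADAMTS4 and ADAMTS5 were well above background on 0 arrays and were not tested.

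Proteinase inhibitors rose in 5 of 11 measured members, with 5 adjusted over the list alone. The elastase inhibitor PI3 rose at least 5.17-fold, SERPINA1 (alpha-1 antitrypsin) at least 2.02-fold and SERPINB8 by 1.41 ± 0.20. SERPINB1 and SERPINE2, named after their values were seen, were the other risers, with 0.55 and 0.45. TIMP1 and TIMP3, inhibitors of metalloproteinases, did not pass: TIMP1 differed by -0.16 ± 0.15 (limma adjusted p = 0.607) and TIMP3 by 0.54 ± 0.27 (limma adjusted p = 0.297). With title series as a block, TIMP3 passed (limma adjusted p = 0.000995) and TIMP1 did not (limma adjusted p = 0.0679), and 6 members of the list rose and 2 fell. Those 2, TIMP2 and RECK, were named after their values were seen and differed by -0.23 and -0.41 (limma adjusted p = 0.0229 and 0.0239 with the block). The list median was 0.45 (camera adjusted p = 0.00122, and adjusted p = 0.0537 with an estimated correlation).

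Interferon-induced genes rose in 35 of 35 measured members, with 35 adjusted over the list alone. IFIT2, an antiviral protein that binds RNA, rose by 6.32 ± 0.17, which is 80.0-fold (limma adjusted p = 5.78e-07). OASL and MX2, likewise antiviral, rose at least 45.1-fold and at least 44.6-fold, and by another kept probe OASL rose at least 8.45-fold. The group had a median of 4.00 (camera adjusted p = 5.46e-61, and adjusted p = 0.0231 with an estimated correlation). Genes of major histocompatibility complex class I presentation rose in 9 of 16 measured members, with 11 adjusted over the list alone. TAP1 and TAP2, the subunits of the peptide transporter, rose by 3.41 ± 0.24 and 2.64 ± 0.14, and the immunoproteasome subunit PSMB9 by 3.21 ± 0.22. That list's median was 1.06 (camera adjusted p = 1.29e-12, and adjusted p = 0.0143 with an estimated correlation). Leukocyte markers gave 4 measured members, of which 0 changed by limma over all genes, adjusted over the list alone or at an unadjusted p under 0.05, and 1 rose and 1 fell with title series as a block.

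In the AP-1 family, 5 of 13 measured members rose, with 5 adjusted over the list alone. BATF2 rose at least 6.73-fold, BATF3 at least 3.84-fold and ATF3, a stress-induced repressor, by 2.50 ± 0.16. MAFF and JUNB, named after their values were seen, rose by 2.05 and 1.62. JUN differed by 0.43 ± 0.15 (limma adjusted p = 0.154) and FOSL1 by 0.63 ± 0.29 (limma adjusted p = 0.264), and both passed with title series as a block (limma adjusted p = 0.000718 and 0.00136). FOS was well above background on 1 control and 1 IL-1 array and was not tested. Its members had a median of 0.43 (camera adjusted p = 3.89e-06, and adjusted p = 0.0231 with an estimated correlation). Of 18 measured immediate early genes, 1 rose, IER3, well above background on 2 of 3 control arrays, by 2.80 ± 0.35, and 1 did so adjusted over the list alone (camera adjusted p = 0.169).

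Complement and acute phase genes rose in 7 of 13 measured members, with 7 adjusted over the list alone. Complement factor B, CFB, rose at least 19.6-fold. The serum amyloid genes SAA1 and SAA2 rose at least 14.0-fold and at least 3.19-fold, but they are near-identical copies, by 2 other kept probes SAA1 rose at least 7.67-fold and at least 1.27-fold, and limma's adjusted p for SAA2 reached 0.0646 without IL-1 replicate 2. The median of the list was 1.71, or 0.88 with genes at their bounds (camera adjusted p = 7.69e-08, and adjusted p = 0.0361 with an estimated correlation). Adhesion molecules rose in 7 of 19 measured members, with 7 adjusted over the list alone (camera adjusted p = 9.28e-06, and adjusted p = 0.0231 with an estimated correlation). CEACAM1 rose by 3.01 ± 0.29, or at least 4.57-fold and by 2.26 by its other kept probes, and NINJ1 by 2.69 ± 0.33. VCAM1, which binds leukocytes, rose at least 2.36-fold, with limma adjusted p = 0.0123 that reached 0.0579 without IL-1 replicate 1.

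Of 16 measured genes of the IL-1 receptor and its proximal signalling, 3 rose and 1 fell, with 4 rises and 1 fall adjusted over the list alone. IL1RN, which encodes the receptor antagonist, rose at least 12.2-fold, or at least 3.09-fold by another kept probe. IRAK2 and MYD88, components of the receptor complex, rose by 3.44 ± 0.19 and 2.20 ± 0.13. PELI2, named after its value was seen, fell by 1.25 ± 0.29. The list median was 0.11 (camera adjusted p = 0.00325, and adjusted p = 0.0581 with an estimated correlation). IL1R1 was well above background on 1 control and 1 IL-1 array and IL1R2 on 0 arrays, so neither was tested.

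Metallothioneins and zinc transporters rose in 7 of 12 measured members, with 7 adjusted over the list alone (camera adjusted p = 1.58e-07, and adjusted p = 0.0216 with an estimated correlation). The zinc importers SLC39A14 and SLC39A8 rose by 2.74 ± 0.14 and 1.32 ± 0.21, and the metallothionein MT1G, which has near-identical relatives, by 1.35 ± 0.18. In hyaluronan metabolism 3 of 8 measured genes rose, also adjusted over the list alone (camera adjusted p = 3.47e-04, and adjusted p = 0.0449 with an estimated correlation). TNFAIP6, which encodes the hyaluronan-binding protein TSG-6, rose at least 53.7-fold, the hyaluronan-degrading CEMIP by 2.52 ± 0.30 and the receptor CD44 by 1.19 ± 0.11, or by 1.83 by another kept probe. Of 15 oxidative stress genes 1 rose, the mitochondrial superoxide dismutase SOD2, by 3.76 ± 0.12 (by 4.42 and at least 3.57-fold by 2 other kept probes), and 1 rose and 1 fell adjusted over the list alone. That list's median was -0.01 while its mean was 0.18 (camera adjusted p = 0.336).

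In hypoxia and glycolysis 5 of 31 measured genes rose, with 5 adjusted over the list alone (camera adjusted p = 4.37e-05, and adjusted p = 0.0581 with an estimated correlation). The vasodilator peptide gene ADM rose by 1.36 ± 0.18 and the hexokinase HK2 by 1.27 ± 0.18, or by 1.93 by another kept probe. PFKFB4 rose by 1.31 ± 0.28 (limma adjusted p = 0.0267). Its limma adjusted p reached 0.116 without IL-1 replicate 1 and was 1.53e-08 with title series as a block. HIF1A and EGLN1, the other risers, were named after their values were seen. Of 16 apoptosis regulators 4 rose, or 5 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.0155, and adjusted p = 0.184 with an estimated correlation, and camera's adjusted p reached 0.0682 without IL-1 replicate 1). The inflammatory caspases CASP1 and CASP4 rose by 2.49 ± 0.30 and 1.46 ± 0.21. BID rose by 1.22 ± 0.25, with limma adjusted p = 0.0235 that reached 0.0991 without control replicate 2, and MCL1, named after its value was seen, was the other riser. In the unfolded protein response 2 of 19 genes rose, also adjusted over the list alone, DNAJB9 by 1.13 ± 0.22 and PPP1R15A by 0.77 ± 0.13 (camera adjusted p = 0.00605, and adjusted p = 0.335 with an estimated correlation, and 0.0784 without IL-1 replicate 3). Their limma adjusted p reached 0.0883 without control replicate 1 and 0.0534 without control replicate 2.

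Of 7 measured genes of prostanoid and nitric oxide synthesis and reception 1 rose, or 3 adjusted over the list alone. PTGS2, the inducible cyclooxygenase, rose at least 1.35-fold, from 4.97 ± 0.36 to 6.39 ± 0.23 (SD, n = 3 each). Its limma adjusted p was 0.0213, reached 0.0965 without control replicate 1, and held in 2 of the 6 fits that left out an array. The group had a median of 0.84, or 0.23 with genes at their bounds (camera adjusted p = 0.0279, adjusted p = 0.133 with an estimated correlation, 0.0504 with title series as a block, and 0.0881 without control replicate 3).

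**Figure D2:**
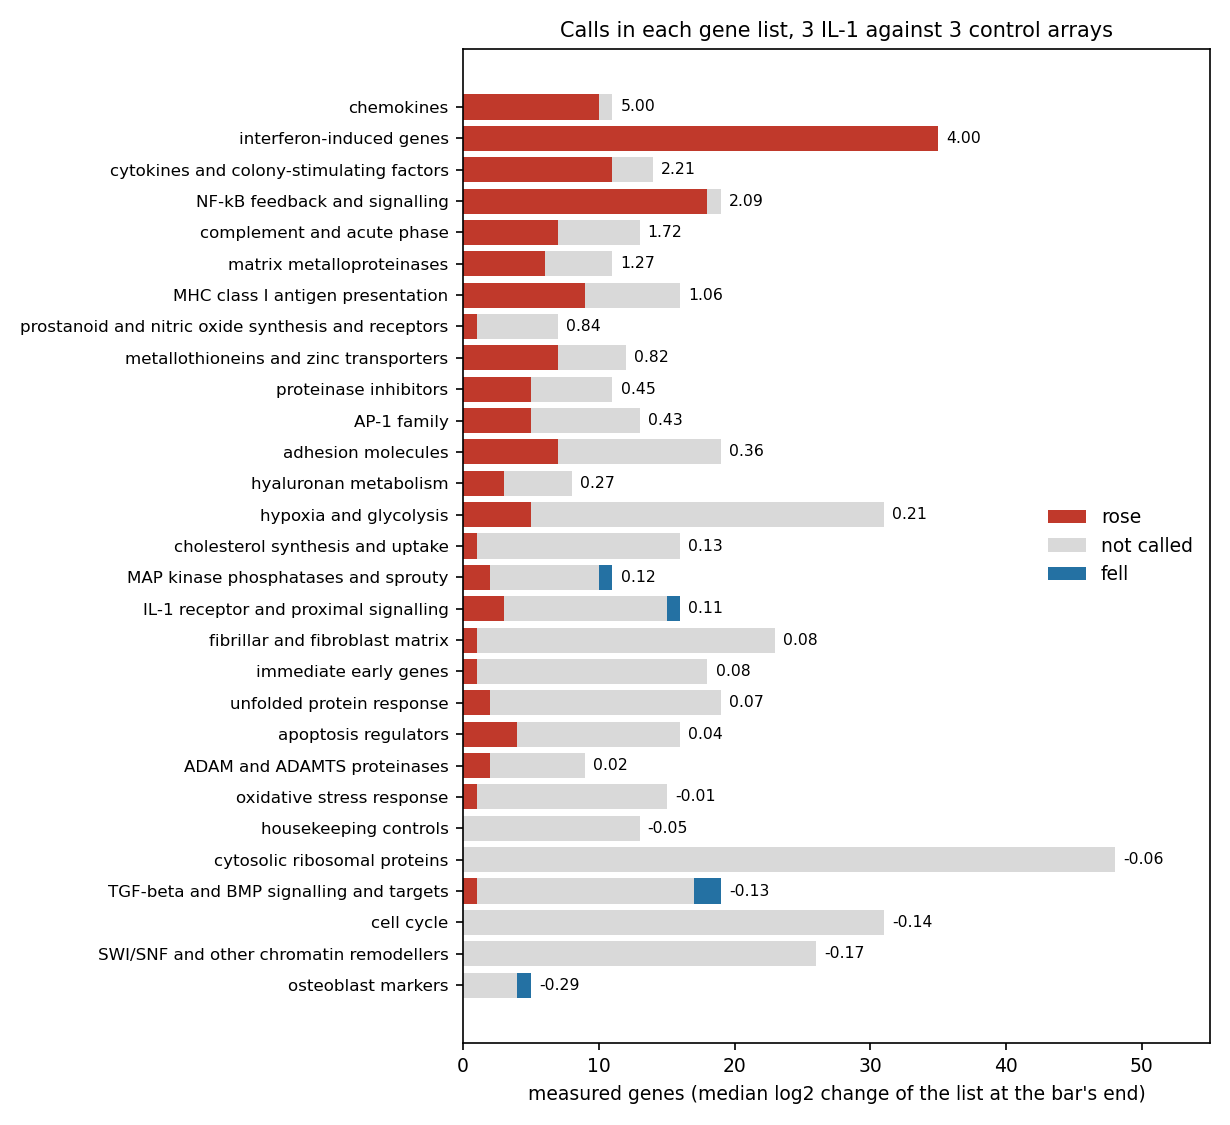
Number of measured genes that rose, fell or were not called in each of the 29 lists with at least 5 measured genes, ordered by median log2 fold change, which is printed at the end of each bar. All 35 measured interferon-induced genes rose, with a median of 4.00, and the osteoblast markers at the bottom had a median of -0.29.

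Cartilage genes were mostly near or below background. SOX9, the transcription factor of the chondrocyte lineage, fell by 0.94 ± 0.18 (limma adjusted p = 0.0186). Its adjusted p reached 0.0946 without control replicate 2 and held in 2 of the 6 fits that left out an array, and it was 7.13e-05 with title series as a block. Of the cartilage matrix and chondrocyte regulators 3 were measured, of which 0 rose and 1, SOX9, fell, also adjusted over the list alone, and the list was too small to test. ACAN, which encodes aggrecan, and COL2A1, which encodes type II collagen, were well above background on 0 arrays. Among 5 osteoblast markers 1 fell, the homeobox gene DLX5, which fell by 1.70 ± 0.25, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.253).

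The 10 genes with the lowest fold changes as fitted included PDE5A, the cGMP phosphodiesterase, which fell by 2.19 ± 0.20 (limma adjusted p = 4.14e-04), while its other kept probe was at least 1.71-fold lower and did not pass (limma adjusted p = 0.0688). RGCC, a regulator of the cell cycle, fell by 2.27 ± 0.33, MAP7D2 fell by 2.06 ± 0.25, PRAG1 fell by 1.96 ± 0.28 and EBF2 fell by 1.92 ± 0.17. REEP1 fell by 1.84 ± 0.30 and CROT, a peroxisomal carnitine acyltransferase, fell by 1.84 ± 0.30. After IL-1, EBF2 and CROT were well above background on 2 of 3 arrays. PDK4 was at least 2.83-fold lower, ZNF629 at least 2.22-fold lower and OR7A5 at least 1.77-fold lower. Without control replicate 1, limma's adjusted p reached 0.112 for ZNF629 and 0.0558 for OR7A5.

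Among 19 genes of TGF-beta and BMP signalling 1 rose and 2 fell, with 2 rises and 4 falls adjusted over the list alone (camera adjusted p = 0.620). BMP2 rose by 1.11 ± 0.20, PMEPA1 fell by 1.01 ± 0.18 and INHBB was at least 1.55-fold lower. Limma's adjusted p reached 0.0582 for BMP2 without IL-1 replicate 2, and 0.0609 for PMEPA1 and 0.129 for INHBB without control replicate 1. Among 11 MAP kinase phosphatases and sprouty genes DUSP6 rose by 1.22 ± 0.19 (at least 2.98-fold by another kept probe), DUSP1 rose by 0.77 ± 0.12 and DUSP14 fell by 0.84 ± 0.12 (camera adjusted p = 0.345 for the list), and 2 rises and 1 fall passed adjusted over the list alone. Limma's adjusted p for DUSP1 reached 0.0538 without IL-1 replicate 1. Of 16 cholesterol genes 1 rose, or 2 adjusted over the list alone: INSIG2, a brake on sterol synthesis, by 1.01 ± 0.14 (camera adjusted p = 0.118). Of 23 fibrillar and fibroblast matrix genes 1 rose, or 0 adjusted over the list alone: DCN, which encodes decorin, by 0.82 ± 0.21, with limma adjusted p = 0.0490 that reached 0.185 without IL-1 replicate 1 (camera adjusted p = 0.143).

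By limma, 0 of 31 cell cycle genes, 0 of 26 genes of SWI/SNF and other chromatin remodellers, 0 of 48 cytosolic ribosomal protein genes and 0 of 13 housekeeping genes changed, and 0 did adjusted over each list alone. At an unadjusted p under 0.05 these counts were 4, 5, 1 and 0. With title series as a block, 1 cell cycle gene rose and 6 fell, 8 chromatin remodeller genes fell, 4 ribosomal protein genes fell and 2 housekeeping genes rose. Camera gave adjusted p = 0.356, 0.0895, 0.345 and 0.653 for these lists. The housekeeping median was -0.05, opposite in sign to camera's direction for that list. Endothelial and epithelial markers had 2 measured members each, of which 0 changed by limma (1 each at an unadjusted p under 0.05), while 1 epithelial marker fell adjusted over the list alone and 1 of each fell with title series as a block.

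In all, camera called 17 of the 29 lists tested upward and 0 downward. Of the 17, 11 kept the call with an estimated correlation, and 16 lists were called with title series as a block. Some called lists had small medians, at 0.04 for apoptosis regulators, 0.07 for the unfolded protein response and 0.11 for IL-1 receptor signalling. In these, 4 of 16, 2 of 19 and 3 of 16 members rose, and 1 of IL-1 receptor signalling fell. Medians were 0.21 for hypoxia and glycolysis, 0.27 for hyaluronan metabolism and 0.36 for adhesion molecules. With fry, which tests whether a list moves 1 way and not whether it moves more than other genes, 18 lists shifted upward and 4 downward. The 4 were chromatin remodellers (fry adjusted p = 0.00479), cell cycle (fry adjusted p = 0.00697), osteoblast markers (fry adjusted p = 0.0139) and ribosomal proteins (fry adjusted p = 0.0178). Their medians were -0.173, -0.135, -0.286 and -0.060, in that order, while the median of all genes tested was -0.107. Camera called 1 list downward, the chromatin remodellers, on the Allstars arrays alone, with array weights, without a detection filter, and with the authors' values and the block.

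In several lists title series as a block raised the number of genes called. With it 15 hypoxia and glycolysis genes rose, 11 adhesion molecules, 7 unfolded protein response genes and 4 prostanoid and nitric oxide genes, and 0 of these lists' members fell. Calls in both directions were 7 rises and 3 falls among fibrillar and fibroblast matrix genes, 5 and 4 among immediate early genes, 3 and 6 in TGF-beta and BMP signalling, and 3 and 3 each among oxidative stress genes and MAP kinase phosphatases. There were 6 rises and 1 fall among apoptosis regulators, 3 and 1 among cholesterol genes, and 2 and 2 among ADAM and ADAMTS proteinases.

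The 2 title series give the same contrast separately, with 2 arrays against 2 and 1 against 1. Of the 1048 genes that rose on the Allstars arrays alone, 1002 were higher in the Sample pair, and of the 1534 that fell there, 1466 were lower, while 38.0% of all genes were higher in that pair. MMP3 differed by 4.68 in the Allstars arrays and 5.55 in the Sample pair, and SOX9 by -1.18 and -0.45. The Sample pair has no replicates of its own, so the p-values of the interaction rest on the spread of the Allstars arrays alone. The difference of the response between series passed for 0 of 9078 genes (limma interaction), with 552 at an unadjusted p under 0.05, and for 45 with the authors' values and 1 without background correction. The chemokine CCL5, singled out after its values were seen, had the lowest interaction p (limma adjusted p = 0.0541), but it was well above background on 0 control arrays, so no size is given for its interaction. Its adjusted p was 8.04e-06 with the authors' values, 0.00130 without background correction and 0.837 without a detection filter.

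**Figure D3:**
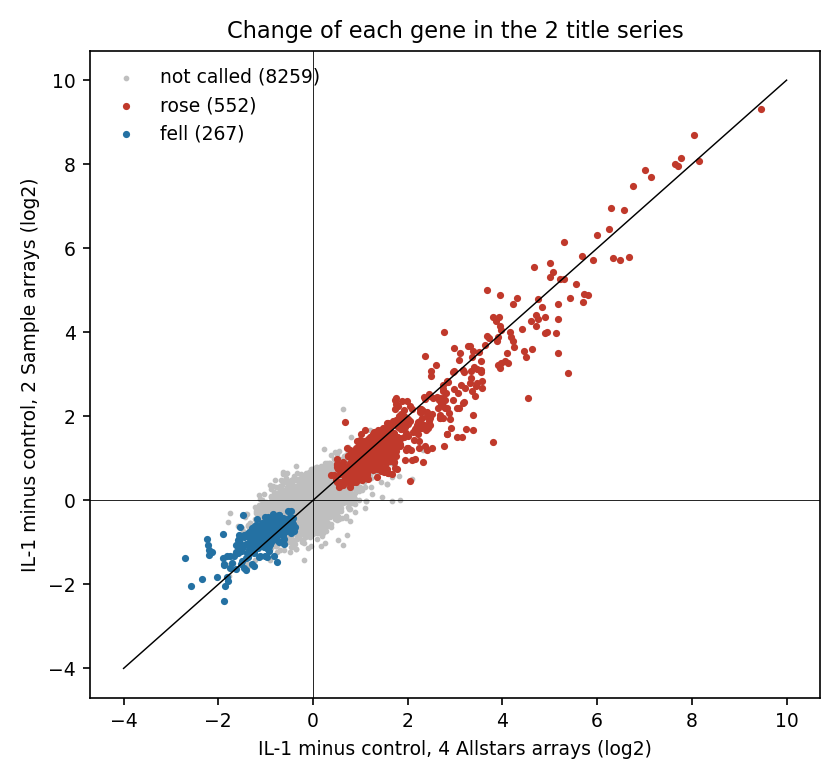
Log2 difference between IL-1 and control for each of 9078 genes in the 4 Allstars arrays (horizontal) and the 2 Sample arrays (vertical), with the line of equality. The 552 genes that rose and the 267 that fell were called on all 6 arrays, these 2 included, so their sides of 0 here follow in part from the call. The r across genes, which are not independent replicates, was 0.905.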

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

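Among probes without a gene name in the annotation used, 25 were well above background on all 3 IL-1 arrays and on none of the control arrays, against 21 the other way round. They are listed because this signal lies outside the genes tested and above the controls. Of the 1609 unnamed probes that passed the detection filter, 62 were higher and 9 lower after IL-1 (limma, adjusted p under 0.05), or 135 and 236 with title series as a block.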

How the results depend on the processing

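The 2 settings that join a title series block with other values were chosen after seeing the data. The 819 genes called became 3196 with title series as a block, 2582 on Allstars arrays alone, 2941 with array weights, 3237 with the authors' values and the block, and 2884 with medians equalised and the block. Leaving out 1 array gave 426 (without IL-1 replicate 1) to 965 (without IL-1 replicate 3) genes. Control replicates 1 and 2 and IL-1 replicates 1 and 2 moved the count by over 1.5 times, to 446, 455, 426 and 465. The 534 genes changed at least 2-fold became 327 with the authors' values, 348 with those and the block, and 324 with detection on all 6 arrays, where 7735 genes were tested. The 17 lists called became 11 with an estimated correlation and 22 (18 up, 4 down) with fry. The interaction count of 0 became 45 with the authors' values and 1, CCL5, without background correction. Fewer arrays alone do not explain the leave-out counts, which were 831 and 965 without control or IL-1 replicate 3, the Sample arrays. A block takes the difference between title series out of the residual spread. Otherwise, beyond fewer genes, the cause was not tested.

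With a replicate block (numbers 1 and 2 of Allstars and the Sample pair), 3323 genes were called. No strong pairing by number was seen within Allstars: the differences between replicates 1 and 2 in the controls and after IL-1 had r = 0.0823 across genes. With 1 such difference per group, a pair effect smaller than the noise of the arrays is not excluded.

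Of 82 named genes, 0 changed sign in any setting that tested them, and 48 were tested with detection on all 6 arrays. A block cannot alter a fold change here. Most named genes had groups without overlap, so leaving out an array could not reverse them. In those settings the sign was thus largely fixed in advance. Of the 78 called, 16 lost the call when some array was left out. Those fits had no block and unequal shares of the title series in the 2 groups. A lost call there does not tell a weak change after IL-1 from the series difference. A slide block was not run, as no slide numbers were used. Signal over background was lowest on IL-1 replicate 2, at 3.19.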

Other observations

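Genes outside the fixed lists, chosen after their values were seen, also rose after IL-1. The guanylate-binding protein GBP5 rose by 4.08 ± 0.22 and GBP3 by 2.15 ± 0.28, and GBP4 rose at least 34.1-fold (limma adjusted p = 1.14e-06). GCH1, the first enzyme of tetrahydrobiopterin synthesis, rose by 4.50 ± 0.25, and IDO1, which degrades tryptophan, at least 5.93-fold. TLR3 rose at least 4.24-fold, TLR7 at least 3.49-fold, AIM2 at least 2.91-fold and NLRP3 at least 5.70-fold, each well above background on no control array. LTB, which encodes lymphotoxin beta, rose at least 15.2-fold and the scavenger receptor OLR1 at least 16.3-fold.

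Several Wnt pathway genes were seen among those that fell, and a list of 91 Wnt genes was then written and tested, so this test was chosen after the pattern was seen. Of 44 measured members 11 fell and 2 rose, or 19 and 6 with title series as a block. The Wnt receptor FZD7 fell by 1.82 ± 0.21, the receptor kinase ROR1 fell by 1.63 ± 0.23 and AXIN2, a feedback inhibitor, fell by 1.21 ± 0.26, whereas RSPO3, which enhances Wnt signalling, rose by 2.00 ± 0.20. The list median was -0.33. The list holds the genes that prompted it, so its camera p of 0.00546 (0.0648 with an estimated correlation) decides nothing, and whether Wnt pathway genes were lower as a group stays open.

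The interferon-induced genes rose together, and 2 tests here were chosen after the result was seen, those on leukocytes as the source of the transcripts and on leukocytes in the IL-1 samples and not in the controls. Quantile normalization was argued against, as the list median was 4.06 without that step. Leukocytes as the main source of the transcripts were argued against by levels on the IL-1 arrays. There the 17 leukocyte markers with a named probe had a median log2 level of 4.96 (upper quartile 6.12). The interferon-induced genes had 11.38 (lower quartile 10.45), a difference of -6.42. Over all genes with several probes and 1 of them at least above background, 2.22% had their 2 brightest probes further apart. The difference sets probes of different genes side by side and is not a measured size, so these levels do not exclude leukocytes as a minor source. The interferon-induced genes had passed the detection filter, as 35 of 37 with a named probe did, and the markers did not need to. A part of the difference may follow from that. The samples are described as SW1353 cells, which are 1 cell line, so the design as described holds no leukocytes. The marker median lies below the lowest signal well above background on these arrays (6.08, 6.28 and 5.94). Of the markers, 10 were well above background on no IL-1 array. Of these markers 23.5% were well above background on all IL-1 arrays, between the bounds of the test planned first, while 0 rose or were well above background on all IL-1 arrays and no control array (with title series as a block CD68 differed by 0.28 and CSF1R by -0.54, limma adjusted p = 0.0106 and 0.00170). Interferon made by the stimulated cells may be a source and cannot be told apart here: 0 of 21 interferon genes were well above background on all 3 IL-1 arrays and no control array, while IFNB1 was so on 1 IL-1 array (mean log2 signal 4.71 in controls and 5.87 after IL-1) and 1 of the IFNA8 probes was above on all 6 arrays (6.94 and 6.89).

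The arrays of the 2 title series differed in 4309 genes with treatment in the model (limma), and the tests of array noise and of brightness without the quantile step were chosen after the result was seen. Noise of single arrays was argued against, as the series difference in controls and in IL-1 arrays had r = 0.818 across genes. Brightness of the scan was argued against as the whole cause, as with medians equalised and no quantile step a smooth curve of the mean level explained 8.92% of the variance of the difference (9.13% in controls and 8.51% after IL-1, under the bound of 10% set for the test). The share of 0.294% with the quantile step decides nothing, since that step removes such a curve. What the title kinds stand for stays open, and no biological explanation was tested.

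With title series as a block more genes fell than rose, and the test of normalization here was chosen after the result was seen. With medians equalised, no quantile step and the block, falls were 52.9% of the calls, so normalization cannot be told apart from a wider fall of transcripts, because the share lies between the bounds set for the test. The median log2 fold change of all genes was -0.11 with the quantile step and -0.05 without it. Both settings bring the arrays to a common level, so neither median measures a wider fall.

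The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 819 genes, 534 at least 2-fold and 17 lists, and the highest of the others gave 0, 0 and 12. In each case 1 of the 10 splits, the real one, gave a result as large. Genes whose groups did not overlap were 28.2% of those tested, against 10% for a single gene with exchangeable arrays. Genes are not independent, and some passed the detection filter only through 1 group, so these shares are not a test.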
